A study of Mus musculus with 8 samples.

How the data were processed

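Nuclei were isolated from the left frontal cortex of mice at postnatal day 30 and run as droplet libraries on the inDrops platform, per the labels' protocols. Control mice carried loxP-flanked Tsc2 alleles without Cre, and mutant mice carried 1 deleted and 1 loxP-flanked Tsc2 allele with SynCre, a Cre recombinase driven by a neuronal promoter. The series holds 8 libraries: 3 from single control animals, 3 from single mutant animals and 2 whose titles each name 2 animals.

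The deposited matrix holds whole-number counts per gene and nucleus, for 21805 genes and 21886 barcodes. Per the labels, reads were placed on genome build GRCm38. The aligner, the counting program, the strand setting, the annotation release and the use of molecular identifiers are not given in the sources used here. The lowest total count of a barcode was between 748 and 753 in each animal, so low-count barcodes had been removed before the counts were deposited. Each barcode name carries an animal name, which assigns every nucleus to 1 of 10 animals, and within the two-animal libraries it assigns each nucleus to 1 of the 2 animals. How the authors told the 2 animals of 1 library apart is not given in the sources used here. The deposited gene identifiers carry no symbols. Symbols for 21741 of them came from the reference gene name table, by exact identifier, and coordinates from the GENCODE M21 annotation of GRCm38.

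The genotype tag calls both two-animal libraries controls, while their descriptions each hold 1 name that ends as the control names do and 1 that ends as the mutant names do. These libraries were therefore left out of the main comparison, which set 3 mutant against 3 control libraries. They entered as alternatives: as controls, following the tag, and as 4 single animals grouped by name ending, which gives 5 animals against 5. Replicate numbers in the text (control 1 to 3 and mutant 1 to 3) follow the order of the samples and pair nothing.

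All computations started from the counts. Barcodes with at least 200 detected genes were kept, which left 21863 nuclei. Scrublet, run per library through scanpy 1.11.5, marked 14 nuclei (0.0640%) as doublets. This is under the 0.5% that had been set as the minimum for acting on the calls, and all nuclei were kept. Counts were scaled to 10000 per nucleus, a pseudocount of 1 was added and the natural log was taken. The 2000 most variable genes picked per library, 30 principal components and 15 neighbours went into Leiden clustering (leidenalg 0.10.2) at resolution 1 with no integration between libraries. Clusters were named from a fixed list of marker genes and took the class with the highest marker score if that was at least 0.4. A cluster that reached this score for no other class was named excitatory where its Slc17a7 level exceeded its Gad1 level. After the clusters had been seen, 2 criteria were added: a cluster stayed unnamed if more of its 10 leading genes were markers of another class, and an excitatory cluster stayed unnamed if its level of Malat1, a nuclear RNA, was under 0.5 of the median over clusters. The cluster that failed the Malat1 criterion is called the low-nuclear-RNA cluster. Excitatory and inhibitory neurons were clustered again to name subclasses. Cell names in the text mean that a cluster carried the markers, not that cells of that kind were sorted.

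For each class, counts were summed per library, and libraries with under 20 nuclei of the class were left out. Genes were filtered with filterByExpr, normalised by TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, R 4.3.3). P-values were adjusted by Benjamini-Hochberg over the genes tested in the class, with a threshold of 0.05. CPM values were computed on the TMM-scaled sum of each class and library. Differences of the genotype effect between classes were tested as an interaction with library as a block. For 35 gene lists fixed before the data were examined, camera from limma 3.58.1 was used with a preset inter-gene correlation of 0.01, adjusted over the lists tested in each class. Shares of nuclei were compared by a two-sided exact permutation test, whose smallest p is 0.1 for 3 libraries against 3 and 0.00794 for 5 animals against 5.

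The genes named in the text follow a rule set before the data were examined. Per class, these were the 10 largest rises and the 10 largest falls by log2 fold change among genes past the threshold with a mean of at least 20 CPM and no overlap between the 3 mutant and the 3 control libraries. Where fewer than 3 genes passed in a direction, the 3 with the smallest p in that direction are given as values. Tsc2, Tsc1, Ccn2, Fos, Arc, Npas4, Bdnf and Hmgcr were always included, and so were up to 6 passing members of each list that passed camera. Mbp and Plp1 were added in oligodendrocytes, Gfap in astrocytes, and Apoe and P2ry12 in microglia. Genes named outside this rule are marked as chosen after their values were seen. Of the 114 genes that were named and past the threshold in a class or subclass, with Tsc2 counted among them, 39 overlap another counted gene in the GENCODE M21 annotation. Their counts are uncertain to the extent that the counting could not part the overlapping genes.

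The test steps were first tested on simulated counts drawn from the means and library sizes of the real libraries, with 200 genes changed by a log2 of 1 or 2. At a log2 of 2, the test recovered 91.5% of the changed genes among 14896 tested in excitatory neurons, 91.6% of those among 10722 in inhibitory neurons, 83.7% of those among 9978 in astrocytes, 69.6% of those among 3442 in oligodendrocytes, 67.4% of those among 4536 in oligodendrocyte precursors and 0% of those among 1537 in microglia, which had 3 control and 2 mutant libraries. At a log2 of 1 the shares were 69.4%, 41.3%, 23.4%, 7.60%, 10.8% and 0% in the same order. In the subclasses, a log2 of 2 was recovered for 86.8% in layer 2/3 neurons (10258 genes tested), 80.7% in layer 6 corticothalamic neurons (8331 genes) and 82.1% in Pvalb neurons (5543 genes). For the difference of effects at a log2 of 2, 63.2% were recovered between excitatory and inhibitory neurons (14229 genes) and 66.0% between excitatory neurons and astrocytes (14047 genes). Of the simulated calls, 8.88% were false in excitatory neurons, 6.72% in inhibitory neurons, 7.84% in astrocytes, 3.175% in oligodendrocytes and 9.21% in precursors. The false share was 7.97% in layer 2/3, 10.8% in layer 6 corticothalamic and 7.62% in Pvalb neurons. It was 8.05% and 6.33% for the differences of effects, in the same order. All but that of oligodendrocytes exceeded the adjusted p threshold, so real calls may hold more false ones than that threshold states.

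Alternatives fixed before the data were examined covered the normalisation, DESeq2 1.42.0 as another test, other filters on genes and nuclei, other clustering resolutions, each library left out in turn, both other uses of the two-animal libraries, other denominators of the shares and other set tests. Alternatives added after the data had been seen left out the 5% of nuclei with the highest doublet scores, left out neuron sub-clusters led by genes of another class, added the low-nuclear-RNA cluster to the excitatory neurons, clustered again without the changed genes, subtracted the low-nuclear-RNA profile as free RNA, added a term for the two-animal libraries, extended the use of 10 animals to further results, and took shares over named nuclei. Clusters for rarer cells (endothelial, mural, fibroblast, newly formed oligodendrocyte and immature neurons) were too small for the comparison in each library and were not tested. Fold changes carry the depth of their class: the summed count per library ran from 3357071 to 8543030 in excitatory neurons and from 33273 to 187364 in microglia. Spreads and standard errors cover counting error and differences between animals only. Intervals of medians are 95% order-statistic intervals over genes. They treat genes of the same animals as independent and do not cover differences between animals.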

Results

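Single-nucleus RNA counts were available for 8 libraries of mouse frontal cortex at postnatal day 30. Single animals gave 6 of them, 3 controls (Tsc2fl/fl SynCre-) and 3 mutants (Tsc2del/fl SynCre+), and the other 2 libraries held 2 animals each. The total counts of the nuclei used were 7248354 for control 1, 11705985 for control 2, 6134637 for control 3, 15327395 for mutant 1, 10898326 for mutant 2 and 8198708 for mutant 3. The two-animal libraries held 18098544 and 21876444 counts. The number of nuclei in a single-animal library ran from 826 in control 3 to 3363 in mutant 1. The median count per excitatory nucleus was 8434 ± 3295 in controls and 6920 ± 816 in mutants (SD, n = 3 each), so the spread between control libraries exceeded the difference between the groups.

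Tsc2, the targeted gene (ENSMUSG00000002496, GRCm38 chromosome 17, 24595816 to 24632630), was examined first because its level bears on the labels. Over all nuclei of a library it reached 21.5 ± 3.95 CPM in controls and 14.95 ± 1.11 CPM in mutants (SD, n = 3 each), from 123 to 233 counts per library. The 3 mutant libraries lay below the 3 control libraries. The log2 fold change was -0.52 with a standard error of 0.17, and it did not pass the threshold in edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p 0.117 over 17245 genes). Over the 10 animals by name it was -0.47 with an edgeR adjusted p of 0.0599, and with a term for the two-animal libraries it passed at -0.47 (edgeR adjusted p 0.0494 for the Tsc2 level). In the two-animal libraries the control-named animals had 18.0 and 21.3 CPM and the mutant-named animals 14.6 and 15.6 CPM. Which exons the alleles lack is not given in the sources used here, and a count of tags near the 3′ end does not measure a deletion elsewhere in the gene. Tsc2 also overlaps Pkd1 on the opposite strand, and the counting is not stated to use strand. Within excitatory neurons the log2 fold change of Tsc2 was -0.38 (adjusted p 0.544) and within inhibitory neurons 0.14 (adjusted p 0.946), both by edgeR. In the low-nuclear-RNA cluster Tsc2 stood at 34.7 CPM in controls and 14.6 CPM in mutants, a difference that was not tested. The fall over all nuclei therefore does not rest on the named neurons alone.

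**Figure D1:**
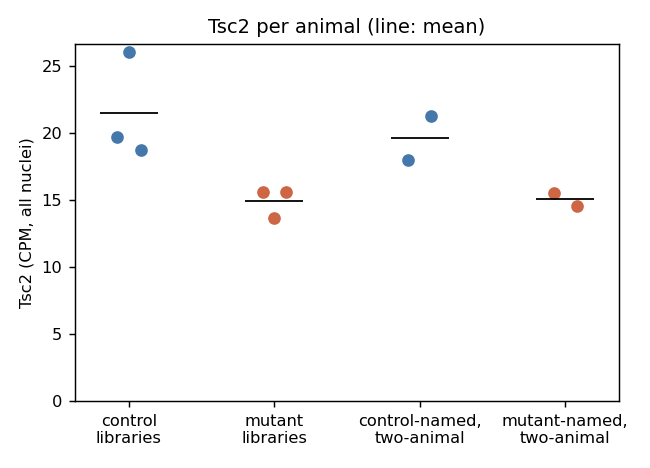
Tsc2 level in CPM over all nuclei (vertical axis) for each animal, with a line at the mean, for the control and mutant single-animal libraries and for the animals of the two-animal libraries grouped by name. The mutant libraries average 14.95 CPM and the control libraries 21.5 CPM.

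Sex-linked transcripts were used to see whether animal names within a library go with distinct nuclei. In two-animal library 1 the control-named animal had 5.89 CPM of Xist and 90.8 CPM of Ddx3y, and the mutant-named animal had 1782 CPM of Xist and 0.169 CPM of Ddx3y. Both animals of two-animal library 2 had Xist levels typical of females, 2358 and 1846 CPM. Each group of 3 single-animal libraries had 1 library with high Xist (1692 CPM in control 1 and 1482 CPM in mutant 2), so sex was balanced in the main comparison.

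The main question was which transcripts differ between mutant and control within each class of nuclei, since SynCre acts in neurons while glia surround them. Mutants also carry a deleted Tsc2 allele that controls lack, and their glia can carry it too. Effects of that allele, of SynCre and of neighbouring mutant neurons cannot be told apart in glia here. In excitatory neurons, 40 of 14793 genes passed the threshold, 38 higher and 2 lower in mutants, from 1701 control and 2274 mutant nuclei. In inhibitory neurons 18 of 10732 passed, 10 higher and 8 lower. In astrocytes 31 of 9983 passed, 19 higher and 12 lower. In oligodendrocytes 46 of 3347 passed, 28 higher and 18 lower. In oligodendrocyte precursors 7 of 4611 passed, 1 higher and 6 lower. In microglia edgeR called 0 of 1298 genes, with 53 at an unadjusted p under 0.05, in 3 control and 2 mutant libraries, and DESeq2 called 1. Each gene called in a class had no overlap between its mutant and control libraries. Among all genes tested the share without overlap was 16.4% in excitatory neurons, 14.7% in inhibitory neurons, 17.2% in astrocytes, 18.3% in oligodendrocytes, 14.4% in oligodendrocyte precursors and 20.6% in microglia, where chance gives 10% for 3 against 3 libraries and 20% for the 3 against 2 of microglia.

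**Figure D2:**
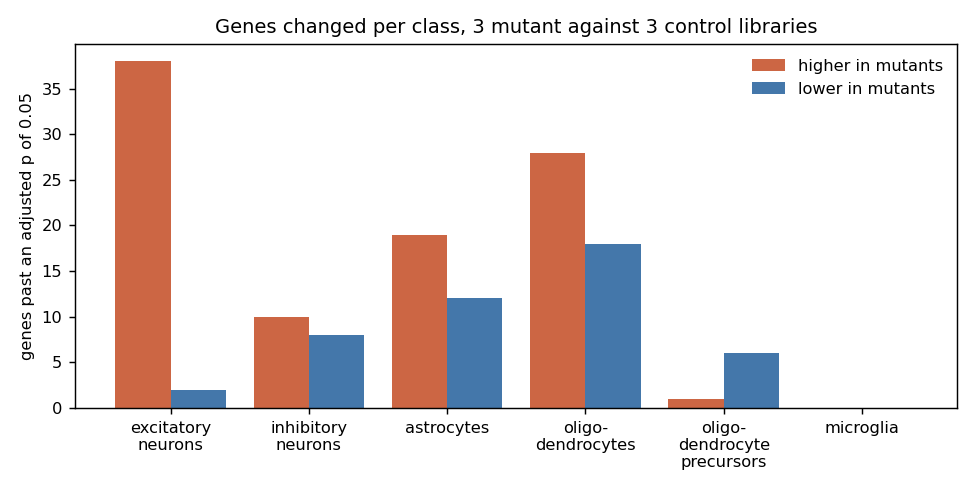
Number of genes past an adjusted p of 0.05 (vertical axis) per class of nuclei, higher (orange) or lower (blue) in 3 mutant against 3 control libraries, with 2 mutant libraries in microglia. Excitatory neurons had 38 higher and 2 lower genes.

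The count of calls depended on which animals entered. With the 10 animals grouped by name, edgeR called 105 genes in excitatory neurons, 89 in inhibitory neurons, 10 in astrocytes, 117 in oligodendrocytes, 8 in oligodendrocyte precursors and 0 in microglia. Of the genes called from the 6 libraries, 30 of 40, 15 of 18, 8 of 31, 39 of 46 and 5 of 7 were also called from the 10 animals, in excitatory neurons, inhibitory neurons, astrocytes, oligodendrocytes and oligodendrocyte precursors. The animals of the two-animal libraries, which took no part in the main test, moved in the same direction by name for 39 of 40 called genes in excitatory neurons, 16 of 18 in inhibitory neurons, 16 of 31 in astrocytes, 46 of 46 in oligodendrocytes and 7 of 7 in precursors. Genes that were not called did so in 60.5%, 57.6%, 50.3%, 60.7% and 53.2% of cases. With the two-animal libraries taken as controls, following their genotype tag, edgeR called 0 genes in excitatory and 0 in inhibitory neurons, 4 in astrocytes, 29 in oligodendrocytes and 2 in precursors. Single libraries mattered too. Excitatory neurons had 12 called genes without control 1, 13 without control 2, 7 without mutant 1 and 12 without mutant 3. Inhibitory neurons had 34 without control 3, 8 without control 1, 28 without control 2, 10 without mutant 2, 1 without mutant 3 and 0 by edgeR without mutant 1. Astrocytes had 1 without mutant 1, 4 without mutant 2 and 1 without mutant 3. Oligodendrocytes had 16 without control 2, 13 without mutant 1, 11 without mutant 2 and 14 without mutant 3, and precursors had 20 without control 1 and 1 without mutant 2.

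In excitatory neurons the largest rise among called genes with a mean of at least 20 CPM was that of Rec114 (ENSMUSG00000074269, chromosome 9, 58652850 to 58743964), from 7.17 ± 8.23 to 43.9 ± 9.40 CPM (SD, n = 3 each). Its log2 fold change was 2.40 with a standard error of 0.46 (edgeR adjusted p 0.0471). Rec114 overlaps Nptn on the opposite strand. Ly86 (chromosome 13, 37345208 to 37419036) rose from 16.0 ± 12.4 to 65.1 ± 13.9 CPM, a log2 fold change of 2.10 (SE 0.35, edgeR adjusted p 0.0263). The smallest adjusted p was that of Sst (chromosome 16, 23889573 to 23890958), at 0.000723 by edgeR, with a rise from 53.3 ± 12.96 to 165 ± 16.9 CPM and a log2 fold change of 1.64 (SE 0.15). The other named rises were Btk (1.76), Ggt5 (1.73), Hbb-bt (1.42), Igfbp5 (1.31), Hbb-bs (1.31), Adgrg6 (1.30) and Hba-a1 (1.22), each as log2 fold change. The haemoglobin genes have near-identical copies, and their single values are uncertain. The 2 falls were Sstr2 (-0.71) and Pxdn (-0.69), both with an adjusted p of 0.0471, and Cnp (-0.85) had an adjusted p of 0.0528. The passing members of passing lists were Cox6a2 (3.01, at a mutant mean of 6.52 CPM), Slc7a3 (1.82), Npy (1.19), Gad1 (1.05) and Nefm (1.02). Of the genes always given, Bdnf (0.47), Tsc1 (0.14), Hmgcr (-0.17), Npas4 (-0.21), Arc (-0.24), Fos (-0.42) and Ccn2 (-0.97) did not pass, with adjusted p between 0.392 and 0.936. Arc ranged widely within the groups, 67.2 ± 50.4 CPM in controls and 59.2 ± 56.7 CPM in mutants.

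**Figure D3:**
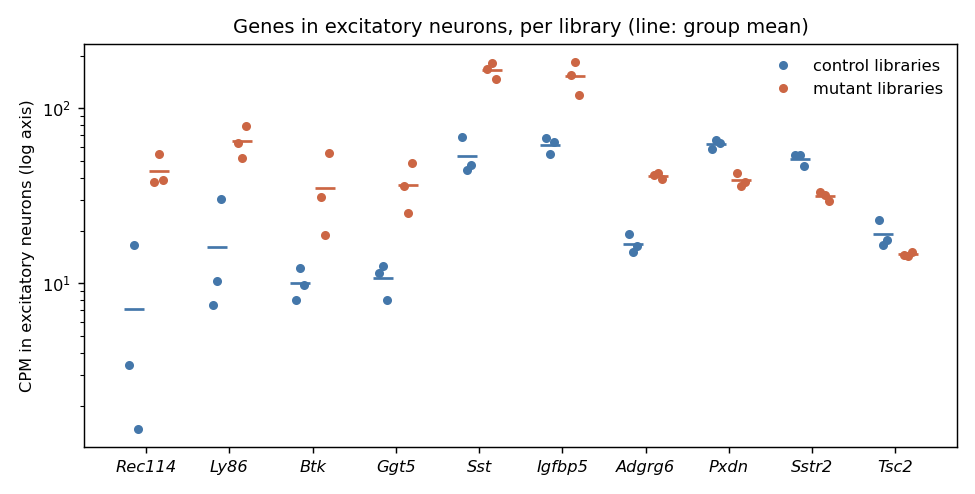
CPM in excitatory neurons (vertical axis, log scale) for each of 3 control and 3 mutant libraries, with a line at the group mean, for 9 named genes and Tsc2. For the 9 genes each mutant library lies on the same side of all control libraries, as for Sst from 53.3 to 165 CPM.

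The rises in excitatory neurons were set beside the low-nuclear-RNA cluster, whose nuclei hold little Malat1 and whose profile is a gauge of RNA from outside the nucleus. Of the 38 genes that rose, 18 had a mutant mean in excitatory neurons at or below the mutant mean of that cluster and 20 had one above it. Sst, at 165 CPM in mutant excitatory neurons, stood at 1063 CPM in the cluster in mutants, and Igfbp5 at 153 against 734 CPM. Rec114 stood at 43.9 against 17.0 CPM, Ly86 at 65.1 against 25.1 CPM and Ggt5 at 36.6 against 2.48 CPM.

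In inhibitory neurons the named rises, 9 of the 10, were Gm16272 (2.24), Mybpc1 (2.10), Btk (1.83), Igfbp5 (1.58), Ankfy1 (1.31), Fam19a1 (1.01), Pex5l (0.94), Sgcz (0.80) and Fam135b (0.76), as log2 fold changes. Mybpc1 (chromosome 10, 88518279 to 88605152) rose from 13.95 ± 0.471 to 59.2 ± 9.36 CPM (SD, n = 3 each; SE of the log2 fold change 0.29, edgeR adjusted p 0.00834). Fam19a1 was lower, not higher, in the mutant-named animals of the two-animal libraries (log2 difference -0.55). The falls were Tac2 (-1.75), Pdyn (-1.58), Tmem130 (-1.02), Elfn1 (-0.96), Parm1 (-0.92), Chl1 (-0.73), Kit (-0.72) and Nxph1 (-0.67). Parm1 (chromosome 5, 91517615 to 91626894) fell from 390 ± 71.0 to 206 ± 12.98 CPM (SE 0.15, edgeR adjusted p 0.0149). Tac2 showed no fall between the animals of the two-animal libraries (log2 difference 0.040). Bdnf (1.22) and Ccn2 (1.19) did not pass, with adjusted p of 0.212 and 0.507, and neither did Tsc1 (0.25), Hmgcr (-0.0038), Fos (-0.13) and Arc (-0.26).

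In astrocytes the 10 largest rises with a mean of at least 20 CPM were C77080 (2.67), Pvalb (1.68), Nefm (1.66), Cycs (1.56), Gm20604 (1.35), Tfrc (1.04), Cplx1 (0.97), Nefl (0.94), Serpini1 (0.91) and Ywhah (0.88), with Syn2 (0.86), Tubb2a (0.78), Tuba1a (0.74) and Stxbp1 (0.67) as passing members of passing lists. The mutant means of all these genes but C77080 in astrocytes lay below those in the low-nuclear-RNA cluster, as for Nefm with 409 against 944 CPM. The named falls were Arhgef26 (-1.62), Dach1 (-1.62), Id4 (-1.39), Prdx6 (-1.33), Slc7a11 (-1.09), Clu (-0.997), Cst3 (-0.93), Timp3 (-0.83), Mfge8 (-0.79) and Gja1 (-0.68), with Atp1a2 (-0.61). Of these 11 falls, Dach1 alone was also lower in the mutant-named animals of the two-animal libraries (-0.21), while Gja1 was higher there (0.91). Gfap fell from 116 ± 68.9 to 30.7 ± 16.4 CPM without passing (log2 -1.91, SE 0.41, edgeR adjusted p 0.0653) and was higher in the mutant-named animals of the two-animal libraries (2.33). Bdnf (0.90), Ccn2 (0.66), Hmgcr (0.19), Tsc1 (0.11), Arc (-0.61) and Fos (-0.80) did not pass.

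In oligodendrocytes the 10 largest falls were Tmem125 (-1.58), Ablim2 (-1.54), Cd9 (-1.33), 1700047M11Rik (-1.29), Lgi3 (-1.11), Ptgds (-1.10), Reep3 (-1.07), Lpar1 (-1.07), Gpr37 (-1.03) and Erbin (-1.02), with Opalin (-0.92), Mal (-0.75) and Cldn11 (-0.51) from the myelin list. Mal (chromosome 2, 127633226 to 127656695) fell from 11650 ± 1063 to 6923 ± 876 CPM (SD, n = 3 each; SE 0.12, edgeR adjusted p 0.00576). Plp1 (-0.23, adjusted p 0.151) and Mbp (-0.27, adjusted p 0.509) did not pass. The 10 largest rises were Nefh (3.16), Hbb-bs (3.01), Hba-a2 (2.83), Hba-a1 (2.64), Chgb (2.50), Nptx1 (2.23), Hbb-bt (2.21), Disp2 (2.09), Gad1 (1.69) and Scn1b (1.61), with Syn2 (1.57), Nefm (1.51), Tubb3 (1.43), Eno2 (1.38), Sv2b (1.34), Syp (1.12), Cplx1 (1.09) and Cck (1.09) from the passing lists. Apart from the haemoglobin genes, these rises lay below the low-nuclear-RNA cluster in mutants, as for Chgb with 590 against 1614 CPM. Hbb-bs rested on a mutant mean of 1759 ± 2122 CPM. Hmgcr (0.53) and Tsc1 (-0.48) did not pass.

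In oligodendrocyte precursors the falls were Rnf122 (-3.35), Mag (-3.05), Sema5a (-1.98), Enpp6 (-1.86), Nfasc (-1.45) and Plp1 (-1.13), with edgeR adjusted p between 0.00451 and 0.0197. Enpp6 fell from 800 ± 195 to 220 ± 58.2 CPM (SD, n = 3 each). The 1 rise was Sst (1.97), whose mutant mean of 662 CPM lay below the 1063 CPM of the low-nuclear-RNA cluster. C77080 (2.83) and Tfrc (1.87) had the next smallest p among the rises, and with Tsc1 (0.36), Hmgcr (0.33) and Bdnf (-0.45) they did not pass. Rnf122, Enpp6 and Mag are among the 10 leading genes of the small cluster of newly formed oligodendrocytes. In microglia C77080 (4.58), Sst (2.53), Serpini1 (1.72), Fez1 (-2.21), Galntl6 (-2.35) and Pnn (-2.69) had the smallest p, and Hmgcr (-0.094), P2ry12 (-0.26) and Apoe (-0.52) were always given. Their adjusted p lay between 0.802 and 0.987, and these values are not calls. On simulated microglia edgeR recovered 0% of log2 changes of 2 and DESeq2 39.8%, so the count of 0 by edgeR says little about microglia.

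Subclasses were tested where each of the 6 libraries held at least 20 nuclei. Layer 2/3 neurons gave 1 call of 10253 genes, Sst (1.83), against 660 genes at an unadjusted p under 0.05, and with the 10 animals Sst did not pass (1.21, edgeR adjusted p 0.226). Layer 6 corticothalamic neurons gave 29 of 8274, 23 higher and 6 lower. The 10 largest rises there were Epha10 (2.39), Adgrd1 (2.38), Ccnb1 (2.21), Ggt5 (2.03), Igfbp5 (1.89), Ccm2 (1.83), Fam19a2 (1.62), Sst (1.54), Enpp2 (1.52) and Ptchd4 (1.46). The falls were Gm11266 (-2.41), Atp2b4 (-0.82), Dkk3 (-0.81), Garnl3 (-0.60), Atp2b1 (-0.56) and Meg3 (-0.47). Pvalb neurons gave 31 of 5475, 16 higher and 15 lower. The 10 largest rises there were Hmcn1 (3.06), Scpep1 (2.53), Mybpc1 (2.28), Lrrk2 (2.05), Cntnap5c (1.86), Ankfy1 (1.63), C030015E24Rik (1.52), Sgcz (1.46), Cnksr2 (1.30) and Nrg1 (1.10). The 10 largest falls were Lpl (-2.58), Sema5a (-1.92), Cse1l (-1.75), Spon1 (-1.71), Tmem130 (-1.32), Parm1 (-1.24), Tmem151b (-1.23), Slc12a5 (-1.10), Purb (-0.91) and Atp2a2 (-0.86). Cntnap5c had an adjusted p of 2.49e-05 by edgeR. Of the called genes, 29 of 29 in layer 6 corticothalamic neurons and 28 of 31 in Pvalb neurons moved the same way in the two-animal libraries by name.

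Whether the genotype effect differed between classes was tested directly. Between excitatory and inhibitory neurons, 13 of 14100 genes differed in effect, and between excitatory neurons and astrocytes 6 of 14010 did. The largest difference against inhibitory neurons was that of Kctd12 (1.92, SE 0.35, edgeR adjusted p 0.0234). The first count was 3 without control 2, 6 without mutant 1 and 4 without mutant 2. The second was 16 without control 3, 21 without control 1, 2 without mutant 2 and 0 without control 2 or without mutant 1. With the 10 animals grouped by name no gene differed between excitatory neurons and astrocytes by edgeR, where 980 genes had an unadjusted p under 0.05 in the 6 libraries.

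Gene lists addressed the pathways that the mutation and the title of the series point to, mTORC1 signalling, activity and chromatin regulators among them. With camera's preset correlation, 16 of 35 lists passed in excitatory neurons, 12 upward and 4 downward, and with the correlation estimated from the data 0 passed. Upward lists were haemoglobin (median log2 fold change 1.26), heat shock chaperones (0.36), reactive astrocyte (0.30), lysosome and autophagy (0.30), cholesterol synthesis (0.27), neuropeptides (0.26), nuclear-encoded respiratory chain (0.24), glycolysis and HIF1 targets (0.20), ATF4 and amino acid response (0.17), fatty acid synthesis (0.17), axon growth and cytoskeleton (0.12) and GABA signalling (0.049). Downward lists were myelin (-0.46), calcium channels (-0.13), histone methylation (-0.083) and glutamate receptors (-0.081). With the low-nuclear-RNA profile assumed to be the free RNA, its estimated share of excitatory counts was 46.3 to 51.97% in controls and 48.1 to 52.65% in mutants. On that estimate these medians do not describe the neurons alone, and haemoglobin, reactive astrocyte and myelin are lists of other cells. The TSC and mTOR pathway list (median 0.072, 20 of 35 members above 0, camera adjusted p 0.113, 2 members higher adjusted over the list alone, Sesn2 and Pik3r1), activity-regulated genes (-0.052, adjusted p 0.589, with a mean of -0.025 while camera's direction was upward), histone deacetylases and sirtuins (-0.036, adjusted p 0.945), histone acetyltransferases and bromodomain readers (0.0016, adjusted p 0.945), DNA methylation (-0.014, adjusted p 0.748) and chromatin remodellers (-0.11, adjusted p 0.0668) did not pass. In histone methylation 0 of 42 members passed, over all genes or adjusted over the list alone, and 13 members lay above 0. In lysosome and autophagy 0 of 30 members passed over all genes and 6 rose adjusted over the list alone. Cholesterol synthesis had 0 of 24 over all genes and 5 higher adjusted over the list alone.

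In the other classes 9 of 35 lists passed in inhibitory neurons, 16 of 35 in astrocytes, 10 of 32 in oligodendrocytes, 11 of 32 in precursors and 4 of 23 in microglia. Activity-regulated genes passed upward in inhibitory neurons with the preset correlation (median 0.22, camera adjusted p 0.0244) and not with the estimated one (adjusted p 0.479), and 0 of 25 members passed over all genes. With the preset correlation myelin passed downward in oligodendrocytes (-0.34) and in precursors (-1.13), where oligodendrocyte differentiation also passed downward (-0.74), and with the estimated one these did not pass (camera adjusted p 0.244, 0.233 and 0.333). In the same precursors presynaptic release (0.35) and neuropeptides (0.82) passed upward, and the estimated free RNA was 40.5 to 56.1% of counts in controls and 53.4 to 65.4% in mutants. In oligodendrocytes presynaptic release (0.55) and axon growth and cytoskeleton (0.53) passed upward, and with free RNA subtracted Mal (-0.41), Cldn11 (-0.17), Opalin (-0.57) and Plp1 (0.10) did not pass. Astrocyte homeostasis (-0.53) and reactive astrocyte (-0.53) both passed downward in astrocytes, where presynaptic release (0.20) and axon growth and cytoskeleton (0.16) passed upward. The estimated free RNA in astrocytes was 51.1 to 54.4% of counts in controls and 58.9 to 68.1% in mutants, and with it subtracted Gja1 (-0.34) and Atp1a2 (-0.28) did not pass. With the correlation estimated from the data, none of the camera calls held in any of the 6 classes (0 lists), and fry, which tests whether a list moves one way without comparing it with other genes, passed 7 lists in excitatory neurons, 1 in inhibitory neurons, 5 in oligodendrocytes and 0 in the other 3 classes. The 7 were ATF4 and amino acid response (adjusted p 0.0242), lysosome and autophagy, fatty acid synthesis and the TSC and mTOR pathway upward, and myelin, histone methylation and calcium channels downward, the last 6 at an adjusted p of 0.0309. The TSC and mTOR pathway list therefore passed fry and not camera.

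Shares of nuclei per class were compared to see whether composition differed. Oligodendrocytes made up 8.47 ± 2.36% of nuclei in controls and 3.72 ± 0.237% in mutants (SD, n = 3 each), with all 3 mutants below all controls (exact permutation p 0.1, two-sided, the smallest the design allows; adjusted 0.16 over the 8 classes). By name the 10 animals gave 7.82 ± 2.52% against 3.12 ± 0.969%, with the 5 mutant-named animals below the 5 others (exact permutation p 0.00794, adjusted 0.0635). Precursors made up 4.25 ± 0.0701% and 3.09 ± 0.546%, inhibitory neurons 8.81 ± 0.753% and 6.50 ± 0.290%, and striatal projection neurons 8.80 ± 2.74% and 3.43 ± 1.43%, each with 3 mutants below all controls (exact permutation p 0.1). The low-nuclear-RNA cluster held 16.6 ± 6.37% in controls and 39.5 ± 6.65% in mutants, with 3 mutants above all controls (exact permutation p 0.1). Excitatory neurons made up 37.9 ± 6.62% and 28.8 ± 3.56%, astrocytes 7.14 ± 0.317% and 5.88 ± 0.906%, and microglia 1.73 ± 0.734% and 2.19 ± 1.17%, with exact permutation p of 0.2, 0.2 and 0.7. Shares of 1 total move together, so the denominator mattered. Over neurons alone excitatory neurons rose from 68.3 to 74.3%, and over non-neuronal nuclei oligodendrocytes fell from 36.3 to 23.4% with 3 mutants below all controls. Over all named nuclei outside the low-nuclear-RNA cluster, oligodendrocytes went from 10.9 to 6.76% with only 1 mutant below all controls (exact permutation p 0.3).

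**Figure D4:**
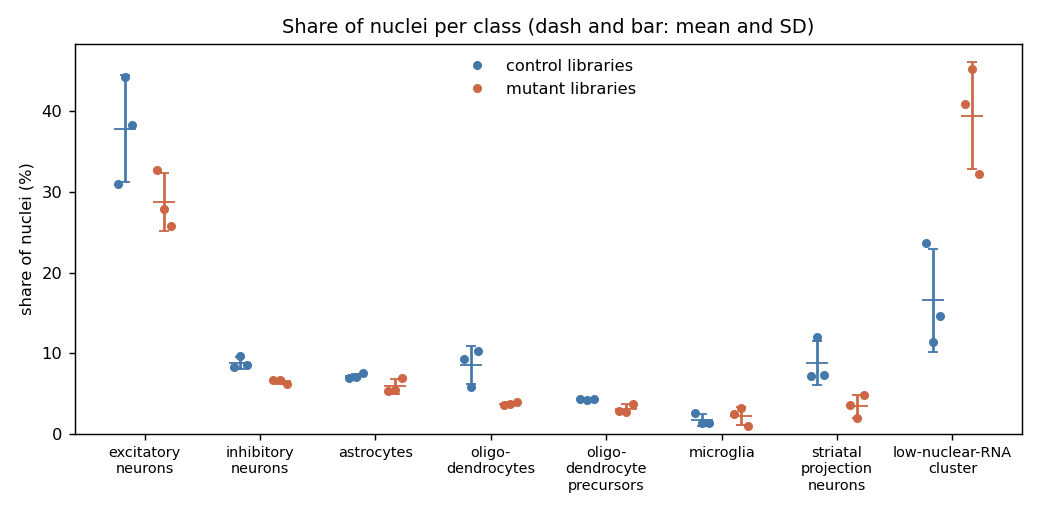
Share of nuclei in percent (vertical axis) per class in each of 3 control and 3 mutant libraries, with dash and bar for the mean and SD. The low-nuclear-RNA cluster averages 16.6% in controls and 39.5% in mutants, and oligodendrocytes 8.47 and 3.72%.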

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

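Of the tests in this part, these were chosen only after the result was seen: all free RNA tests on the rises in excitatory neurons, the doublet test on Sst, the tests of another mix of clusters, of where a sub-cluster ends and of genotype, the ratios over named nuclei, the white matter test, and the tests of clustering and of library preparation on the low-nuclear-RNA cluster.

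The genotype effect differed between excitatory and inhibitory neurons in 13 genes by a test of the difference itself (edgeR). As excitatory minus inhibitory log2 fold changes these were Kctd12 (1.92), Slc6a1 (1.67), Sst (1.66), Slc32a1 (1.54), Gad1 (1.31), Npy (1.23), Serpini1 (0.78), Spock3 (0.73), Atp1b1 (0.59), Kcnip4 (-0.73), Fam19a1 (-0.91), C030015E24Rik (-1.01) and Cntnap5c (-1.32). Of these, Sst, Gad1, Npy, Slc6a1 and Slc32a1 are transcripts of inhibitory neurons, and in mutant excitatory neurons Sst (165 against 1063 CPM), Gad1 (110 against 611 CPM) and Npy (59.6 against 345 CPM) lay far below the low-nuclear-RNA cluster, so free RNA stays open for such differences. With the 10 animals grouped by name Gad1 (0.83, adjusted p 0.0455), Slc6a1 (1.13, 0.0236), Sst (1.27, 0.00322), Serpini1 (0.73, 0.000276), C030015E24Rik (-0.76, 0.0136), Kcnip4 (-0.62, 0.0129) and Cntnap5c (-1.15, 0.0136) passed again, while Npy (0.88, 0.0946), Slc32a1 (0.97, 0.106), Spock3 (0.52, 0.107), Atp1b1 (0.44, 0.0606), Kctd12 (0.58, 0.719) and Fam19a1 (-0.37, 0.691) did not. C030015E24Rik lies within Kcnip4 on the same strand, so these 2 values are not independent. Without control 2 the count was 3, without mutant 1 it was 6 and without mutant 2 it was 4.

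Between excitatory neurons and astrocytes the effect differed in 6 genes, Htra1 (1.52), Mt1 (1.26), Clu (1.13), Cst3 (0.98), Sparcl1 (0.77) and Malat1 (0.68), as excitatory minus astrocyte log2 fold changes. With the 10 animals none of these passed (edgeR adjusted p 0.9995 for each). Without control 2 or without mutant 1 the count was 0, without mutant 2 it was 2, without control 1 it was 21 and without control 3 it was 16.

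Signals also appeared in nuclei and animals outside the main comparisons. In striatal projection neurons, which are outside the planned classes, Igfbp5 rose by 2.79 and Sst by 1.32 on the log2 scale. The low-nuclear-RNA cluster held 22.9 percentage points more of the nuclei in mutants than in controls. In the animals of the two-animal libraries, 20 of 20 genes that rose in excitatory neurons above the level of that cluster were higher in the mutant-named animals.

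The first pattern weighed is the set of 38 rises in excitatory neurons, in 2 parts. For the 18 rises at or below the level of the low-nuclear-RNA cluster, free RNA from other cells is a candidate explanation. The median log2 fold change of these genes in oligodendrocytes, precursors and striatal projection neurons was 0.98, with 40 of 42 values above 0. Doublets with interneurons were looked at for Sst alone, whose log2 fold change was 1.59 without the highest doublet scores and 1.64 with them. Scrublet marked only 14 nuclei, so its scores may not single out such doublets, and these values do not decide the question. Genotype stays open for these 18 genes, of which 17 moved the same way in the two-animal libraries, since free RNA would follow the animal as well.

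For the 20 rises above that level the tables argue against another mix of the 11 excitatory sub-clusters compared here as the whole cause. The Gm38560-led sub-cluster took 11.01 to 11.5% of the excitatory counts in controls and 16.3 to 22.5% in mutants, so the mix did change. With the mix of 11 excitatory sub-clusters held equal between the 6 libraries, the median log2 fold change of the 20 genes was 1.28 (interval 0.94 to 1.74), against 1.33 at the own mix, which a change in that mix alone would not give. The sub-clusters had been drawn without the changed genes, these 20 among them. A shift between kinds of nuclei within a sub-cluster would remain at the equal mix, and it stays open. Merging that sub-cluster with its neighbours left a median of at least 1.70 over the 3 unions tried (interval 0.85 to 2.98 for the lowest). The 20 genes had been called over all excitatory neurons, and each union holds the sub-cluster picked for its rises. The medians therefore decide nothing about a shifted border. Free RNA stays open as a candidate explanation. If it reached all excitatory nuclei of an animal alike, a gene would gain as many CPM in the sub-cluster where controls have most of it as in the others. The median ratio of these gains over the 20 genes was 0.151 (interval -0.64 to 1.24), with no gain in that sub-cluster for 10 genes, so a larger gain there was not seen. For 3 of the 20 genes the highest control level lay in the Gm38560-led sub-cluster. A loss, as in those 10 genes, is not an equal gain either. Picking the highest control level works toward a low ratio, and the value does not show that free RNA is the cause. Across classes, the median ratio of the CPM gained in astrocytes and striatal projection neurons to that gained in excitatory neurons was 0.483 (interval 0.294 to 0.953 over 13 genes), which decides nothing by itself. The effect differed between the Gm38560-led and the layer 2/3 sub-cluster in 11 of the 18 genes with a value, but the former had been picked for its number of rises, so this excludes nothing. Genotype goes with the 20 of 20 genes that were higher in the mutant-named animals, where 60.5% of genes not called moved the same way. Since free RNA would follow the animal as well, both stay open.

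The second pattern is the smaller share of oligodendrocyte nuclei in mutants. A larger low-nuclear-RNA cluster in the denominator is argued against as the whole cause by the ratio of mutant to control shares over non-neuronal nuclei. It was 0.645 (SE 0.0592), with 3 mutants below all controls (exact permutation p 0.1, the smallest the design allows). Over all nuclei the ratio was 0.440, so part of the fall goes with the denominator. Over named nuclei the ratio was 0.622 (SE 0.123), but only 1 mutant lay below all controls (exact permutation p 0.3). A lower recovery of all glia is argued against by the ratios over named nuclei, of which the lower was 1.04 (SE 0.131, precursors) and the other 1.18 (SE 0.133, astrocytes). Less white matter in the mutant dissections and an effect of genotype cannot be told apart, because no layer or region was recorded per nucleus. Striatal projection neurons went from 15.7% of neurons in controls to 8.89% in mutants, with 3 mutants below all controls, so the regions sampled may have differed. Over the 10 animals by name these neurons made up 10.7 ± 3.25% and 8.07 ± 7.39% of all nuclei (SD), which overlap widely. Mal per oligodendrocyte nucleus fell by 0.75 on the log2 scale, which leaves the question open. A different mix of regions could bring other oligodendrocytes (log2 -0.75), and more free RNA in mutants could dilute Mal. With the low-nuclear-RNA profile assumed to be the free RNA, its estimated share of oligodendrocyte counts was 28.4 to 36.6% in controls and 37.0 to 54.6% in mutants, and with it subtracted Mal fell by 0.41 (log2 -0.41, edgeR adjusted p 0.742).

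The third pattern is the larger low-nuclear-RNA cluster in mutants. Clustering on the changed genes is argued against, since the difference was 23.1 percentage points without them. In that clustering 2 clusters, of 3321 and 1087 nuclei, had Malat1 under the limit and were pooled. The first lay at the limit (637.3 against 637.5 CPM). Taken instead by their make-up, 94.5 and 90.8% of their nuclei came from the low-nuclear-RNA cluster, and the difference was 23.15 points. Lower depth in mutants is argued against as the whole cause. The ratio of median counts per excitatory nucleus was 0.821, with a spread between control libraries wider than the difference. Control 1 had a median of 4887, below the mutants (6376 to 7858.5). Clustered without the changed genes, its share was 13.2%, against 32.6 to 45.8% in mutants. The 4 animals of the two-animal libraries had medians of 3237.5 to 5644 and shares of 1.38 to 11.8%. Among the mutants alone the deepest, mutant 3, had the smallest share, and a part for depth is not excluded. The preparation of each library stays open. Within two-animal library 1 the mutant-named minus control-named difference was -0.203 points, and within library 2 it was 10.1 points. Over 10 animals the shares were 10.9 ± 9.05% and 26.6 ± 18.5% (exact permutation p 0.143), and an effect of genotype cannot be told apart from preparation here.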

How the results depend on the processing

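Alternatives chosen after seeing the data were leaving out the highest doublet scores, leaving out doubtful sub-clusters, adding the low-nuclear-RNA cluster, clustering without the changed genes, subtracting free RNA, the library term over 10 animals, the 10 animals for subclasses, differences and lists, and the share of named nuclei. The others were chosen before the data were examined. In all, 201 results were recomputed under 27 settings, giving 3505 values. Apart from leaving out libraries, 128 values of comparisons kept their direction and side of the threshold or, for counts, stayed within 1.5 times the main count, 71 counts moved, 8 reversed and 1 became stronger. Shares of nuclei compared between 3 and 3 libraries could change direction only, since their smallest exact permutation p, 0.1, lies above the threshold. For single genes 1593 kept their direction and side of the threshold, 451 became weaker, 22 stronger and 40 reversed. No paired analysis was possible because the replicate numbers of the 6 single-animal libraries were assigned here and pair nothing, and no litter or batch is given. Each two-animal library holds 1 control-named and 1 mutant-named animal, and the library term over 10 animals compares these within their library. A block for litter was therefore not run, and keeping doublets was void, since no nucleus had been removed as one. Unless stated, the cause was not tested.

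With DESeq2 the counts were 105 in excitatory neurons, 38 in inhibitory neurons, 141 in astrocytes, 17 in precursors and 1 in microglia. With RLE factors in edgeR, no count of a comparison moved. With the two-animal libraries as controls edgeR called 0 genes in excitatory, inhibitory, layer 2/3 and layer 6 corticothalamic neurons, 4 in astrocytes, 29 in oligodendrocytes, 2 in precursors and 8 in Pvalb neurons, and 8 lists passed in microglia; by name these libraries hold mutants among the controls. With the 10 animals by name the counts were 105 in excitatory neurons, 89 in inhibitory neurons, 10 in astrocytes, 117 in oligodendrocytes, 102 in Pvalb neurons and 96 in layer 6 corticothalamic neurons, with 0 differences between excitatory neurons and astrocytes and 8 lists in microglia. With the library term they were 246, 123, 12, 107, 21 and 1 in excitatory neurons, inhibitory neurons, astrocytes, oligodendrocytes, precursors and microglia, and the fall of Tsc2 passed the threshold (-0.47).

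Without a filter on low counts the counts were 128 in inhibitory neurons, 284 in astrocytes, 24 in precursors, 7 in microglia, and 65 and 77 for the differences of excitatory from inhibitory neurons and from astrocytes. With at least 10 CPM in 3 libraries microglia had 5, where fewer genes were tested. With at least 500 genes per nucleus astrocytes had 2. At Leiden resolution 2 inhibitory neurons had 3, astrocytes 2 and precursors 1; at 0.5 oligodendrocytes had 13 and precursors 0 by edgeR. Without the highest doublet scores astrocytes had 1, oligodendrocytes 27, precursors 0, microglia 2 and layer 2/3 neurons 0. Clustered without the changed genes, oligodendrocytes had 26 and layer 2/3 neurons 0. With the low-nuclear-RNA cluster added, excitatory neurons had 636.

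After subtracting free RNA, 0 genes were called in excitatory neurons, inhibitory neurons, oligodendrocytes and precursors and 2 in astrocytes, and 2, 7, 1, 3 and 0 lists passed in excitatory neurons, astrocytes, oligodendrocytes, precursors and microglia. A called gene could be lost in 3 ways. Some had too few counts left to be tested, such as Sst in excitatory neurons and in precursors. Some changed in size, such as Adgrg6 in excitatory neurons (1.30 to 0.75), Slc7a3 in excitatory neurons (1.82 to 1.18), Mal in oligodendrocytes (-0.75 to -0.41) and Cldn11 in oligodendrocytes (-0.51 to -0.17). Others kept their size while the variation between libraries grew. The biological coefficient of variation went from 14.7 to 71.4% in excitatory neurons, 17.2 to 36.8% in inhibitory neurons, 18.3 to 61.8% in astrocytes, 24.9 to 40.3% in oligodendrocytes and 25.8 to 57.97% in precursors. Rec114, for example, went from 2.40 to 2.38 on the log2 scale with an adjusted p of 0.9999. With the correlation estimated by camera, 0 lists passed in each of the 6 classes. With fry, 7 passed in excitatory neurons, 1 in inhibitory neurons, 5 in oligodendrocytes and 0 in the other 3.

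Shares reversed with the denominator, by its construction. As shares of neurons or of non-neuronal nuclei the differences were 5.99 points for the share of excitatory neurons, 0.802 for the share of inhibitory neurons, 5.44 for the share of astrocytes and 0.650 for the share of oligodendrocyte precursors. As shares of named nuclei they were 4.40, 0.634, 1.63 and 0.202. The oligodendrocyte share kept its direction under both.

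Single genes that reversed, none of which passed in the main comparison except where named as called, were as follows. With free RNA subtracted, in excitatory neurons Hmgcr (0.14), Arc (0.34) and Tsc2 (0.97), in inhibitory neurons Hmgcr (0.24), in astrocytes the called Tfrc (-3.95), in oligodendrocytes Plp1 (0.10) and Mbp (0.051), in microglia P2ry12 (0.28). Without a filter, Hmgcr in inhibitory neurons (0.029) and in microglia (0.37) and P2ry12 in microglia (0.14). With the 10 animals by name, Ccn2 (-0.27) and Tsc2 (-0.12) in inhibitory neurons, Tsc1 (-0.020) and Bdnf (0.077) in precursors and Hmgcr in microglia (0.14); with the library term, Tsc2 in inhibitory neurons (-0.11), Bdnf in precursors (0.11) and Hmgcr in microglia (0.21). At Leiden resolution 2, Fos (0.034) and the called Elfn1 (0.14) in inhibitory neurons, Bdnf (0.19) and the called Nfasc (0.070) in precursors and Hmgcr in microglia (0.012); at 0.5, Tsc1 in astrocytes (-0.0052). Without the highest doublet scores, Arc in inhibitory neurons (0.24), the called Nfasc in precursors (0.39), and Hmgcr (1.35) and P2ry12 (0.27) in microglia. Without doubtful sub-clusters, Hmgcr in inhibitory neurons (0.082). With the two-animal libraries as controls, Tsc1 in astrocytes (-0.037), and Hmgcr (0.0094), P2ry12 (0.26) and Apoe (0.10) in microglia. Clustered without the changed genes, Bdnf in precursors (0.026) and Hmgcr in microglia (0.029). With at least 10 CPM, Hmgcr (0.32) and P2ry12 (0.11) in microglia; with at least 500 genes, Hmgcr (1.52) and P2ry12 (0.24) there.

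Leaving out 1 library at a time, with the microglia of mutants then resting in part on 1 library assumed to vary like the others, gave 7 to 42 called genes in excitatory neurons, 0 to 34 in inhibitory neurons, 1 to 36 in astrocytes, 11 to 51 in oligodendrocytes, 1 to 20 in precursors, 0 to 4 in microglia, 10 to 42 in Pvalb neurons, 0 to 2 in layer 2/3 neurons and 12 to 35 in layer 6 corticothalamic neurons. Pvalb neurons had 15 without mutant 1, 19 without mutant 2 and 10 without mutant 3, and layer 6 corticothalamic neurons 15 without control 1, 14 without mutant 1, 19 without mutant 2 and 12 without mutant 3. Of the 40 genes of excitatory neurons, 5 were called again without mutant 1 and 27 without control 3. Differences of effect ranged from 3 to 18 and from 0 to 21. Lists ranged from 13 to 18 in excitatory neurons, 5 to 10 in inhibitory neurons, 7 to 20 in astrocytes, 6 to 12 in oligodendrocytes, 9 to 14 in precursors and 1 to 6 in microglia. The log2 fold change of Tsc2 ranged from -0.62 to -0.34. The difference in points ranged from -12.5 to -5.89 for the share of excitatory neurons, -2.62 to -1.90 for the share of inhibitory neurons, -1.78 to -0.951 for the share of astrocytes, -6.08 to -3.84 for the share of oligodendrocytes, -1.47 to -0.964 for the share of oligodendrocyte precursors and -0.0606 (without mutant 2) to 1.10 for the share of microglia. Single genes that reversed without 1 of the libraries are given as ranges of the log2 fold change: in excitatory neurons Npas4 (-0.85 to 0.49), Arc (-1.22 to 0.43) and Fos (-0.90 to 0.031), in inhibitory neurons Hmgcr (-0.13 to 0.11), Fos (-0.76 to 0.41) and Arc (-0.55 to 0.56), in astrocytes Tsc1 (-0.0074 to 0.23), in precursors Hmgcr (-0.064 to 0.65) and Bdnf (-0.96 to 1.11), and in microglia Hmgcr (-0.53 to 1.35), P2ry12 (-0.30 to 0.018) and Apoe (-0.86 to 0.49), and C77080 in microglia (-0.27 without mutant 1 to 5.72). None of these passed in the main comparison.

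Depth limits what smaller classes can show. On simulated data a log2 change of 1 was recovered for 69.4% of genes in excitatory neurons, 41.3% in inhibitory neurons, 23.4% in astrocytes, 7.60% in oligodendrocytes, 10.8% in precursors and 0% in microglia by edgeR.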

Other observations

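In this part the look at single sub-clusters, the 3 unions of sub-clusters and the splits with a library term were chosen only after results were seen; the counts over the other splits were not.

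Clustered without the changed genes, 1 excitatory sub-cluster, led by Gm38560, had the most called genes of the 8 excitatory sub-clusters tested. It had 778 nuclei, from 21 to 151 per animal, and its markers gave it no name. With the 6 libraries 139 genes were higher and 102 lower in it, and with the 10 animals 326 and 297, while the layer 2/3 sub-cluster had 0 and 0 by edgeR with the 6 libraries. Over the 10 animals, 417 of the 623 called genes had no overlap between the groups. Of 10645 genes tested over the 10 animals, those whose effect differed from the layer 2/3 sub-cluster past the threshold (edgeR adjusted p under 0.05) were counted. Its log2 fold change lay above that of the layer 2/3 sub-cluster in 237 of them and below it in 249. These counts go by the sign of the difference, so a gene that fell more in the Gm38560-led sub-cluster counts among the 249. A sub-cluster can be drawn differently in the 2 groups, so it was merged with its neighbours in 3 ways. With sub-cluster 2 the union held 1129 nuclei with 77 genes higher and 36 lower (6 libraries), with sub-clusters 2 and 7 it held 2093 nuclei with 61 and 15, and with sub-clusters 2 and 12 it held 1324 nuclei with 63 and 18. Ly86 (3.85, 3.55 and 3.82), Rec114 (2.90, 2.98 and 2.997), Adgrg6 (4.04, 4.13 and 3.92) and Ggt5 (3.75, 3.63 and 3.08) passed in all 3 unions. The sub-cluster was picked for its number of rises, and the splits below repeat that pick. For the 20 genes above the level of the low-nuclear-RNA cluster, of which 18 were tested, the median log2 fold change was at least 1.70 over the unions. The effect was compared with that of the layer 2/3 sub-cluster alone, and a difference from the other excitatory sub-clusters was not tested.

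Chance as the source of the counts was examined by other splits of the 10 animals into 5 and 5, with 100 splits drawn, the real one included. In the Gm38560-led sub-cluster 1 split, the real one, gave 326 rises, against 31 at most in the others. In inhibitory neurons 1 gave as many as the real 89 (highest other 13), in oligodendrocytes 1 as many as 117 (4), in excitatory neurons 2 as many as 105 (402), in precursors 2 as many as 8 (50) and in astrocytes 3 as many as 10 (64). For the Gm38560-led sub-cluster, inhibitory neurons and oligodendrocytes, 1 of 100 splits makes chance unlikely without excluding it. The sub-cluster had been drawn without genes called in the real split, and the other splits did not repeat that step. In excitatory neurons, astrocytes and precursors the share was also under 0.05, but other splits gave several times the real count, which points to a structure of the samples. The split with 402 genes put the 4 animals of the two-animal libraries and mutant 1 against the 3 controls and the other 2 mutants. The splits with 64 and 50 genes put 1 animal of the two-animal libraries on one side and 3 on the other, and what lies behind them was not tested. A term for the two-animal libraries was therefore added, and the 40 splits that part the 2 animals of each of these libraries were counted. The real split and the highest other gave 246 and 18 genes in excitatory neurons, 123 and 3 in inhibitory neurons, 107 and 5 in oligodendrocytes and 21 and 1 in precursors, with 1 split, the real one, giving as many in each. Chance is unlikely there but not excluded by 40 splits. In astrocytes the real split and the highest other gave 12 and 29, with 2 splits giving as many, and chance stays open.

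The 10 splits of the 6 libraries are too few for a share under 0.05. The real split and the highest other gave 40 and 3 genes in excitatory neurons, 18 and 0 in inhibitory neurons, 31 and 0 in astrocytes, 46 and 0 in oligodendrocytes, 7 and 0 in precursors, 29 and 1 in layer 6 corticothalamic neurons and 31 and 1 in Pvalb neurons, each with 1 split giving as many. In layer 2/3 neurons they gave 1 and 3, with 4 splits giving as many. For differences of effect they gave 13 and 0 against inhibitory neurons and 6 and 1 against astrocytes, with 1 split each. For gene lists they gave 16 and 12 in excitatory neurons, 16 and 9 in astrocytes, 10 and 8 in oligodendrocytes and 11 and 7 in precursors, with 1 split each, and 9 and 9 in inhibitory neurons, with 2 splits.

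Of 114 named genes called in a class, with Tsc2, 39 overlap another counted gene. Among them Rec114 overlaps Nptn, Gm16272 overlaps Adck2 and Ndufb2, C77080 overlaps Yars, and Sstr2 overlaps Slc39a11. Where strand was not used in counting, tags of 1 gene can be counted for the other.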
